A study of Homo sapiens with 4 samples.

How the data were processed

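Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for FOXA2 was carried out in PC3 cells given vehicle or GSK2879552. Per the labels, each group comprised 2 samples whose titles end in lane numbers and which are described as technical replicates. The labels of both samples of a group name the same peak list, so the data analysed here were 2 peak lists, 1 per group, each covering both lanes. The sample descriptions call the assay ATAC-seq, whereas the titles and the series call it FOXA2 ChIP-seq; the latter was followed. Per the labels' protocols, cells were kept in medium with 5% charcoal-stripped serum and received 50 µM GSK2879552 for 4 hours, and libraries were made with a ThruPLEX kit. The duration of the vehicle treatment is not stated separately.

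Per the submitters' processing notes, BWA 0.7.2, SAMtools 0.1.18 and MACS2 2.1.2 were used with the hg19 (GRCh37) build; their options, the calling threshold, the handling of duplicates and the use of a control library are not given in the sources used here. The deposited lists give, per peak, an interval, a summit and the peak caller's values. The deposited fold enrichment is the ratio of fragments at the summit to the local background, with 1 added to both. The deposited −log10 p-value and −log10 q-value were computed by the authors' peak caller against that background, and the deposited score is 10 times the −log10 q-value as a whole number. The summit offset was used as deposited. All peak scores and folds cited are the authors' values. They were used to describe, rank and filter peaks, with the same limits set in both lists where counts under a limit are compared; a fold or −log10 p is not compared between the lists. Each interval had 1 summit. In the authors' deposited table of each list the lowest −log10 q was 1.39 in the vehicle list and 1.66 in the GSK2879552 list.

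The number of sequenced fragments covering each summit, and the local background, were computed from the fold and the −log10 p. MACS2 defines the fold as fragments plus a pseudocount of 1 over background plus 1, and p as a Poisson upper tail. For each peak the whole number of fragments under 1500 that gave the deposited p was sought. A whole number matched within 0.001 in −log10 p for 100% of peaks in both lists, with a largest error of 0.000135. A second whole number also lay within that tolerance for 3 vehicle and 7 GSK2879552 peaks, for which the better match was used. On simulated summits the fragment number was recovered for 100% of 2981 drawn for the vehicle list and 100% of 2948 drawn for the GSK2879552 list. The shortest intervals, 175 bp in the vehicle list (1687 peaks) and 168 bp in the GSK2879552 list (1349 peaks), were taken as the fragment length the peak caller used, because MACS2 by default reports no shorter interval. Above the floor, 100% of local backgrounds in both lists were whole multiples (within 0.05 of a step) of that length divided by 10000 bp. This is the step 1 unscaled read adds to a 10 kb window. The floor of the background, 1.079 fragments per position in the vehicle and 1.082 in the GSK2879552 library, divided by the fragment length, gave the reads per kb of genome. Reads per kb, as a measure of depth, assume that the background was made from the immunoprecipitated library itself and not from a control library, which no source used here states. Ratios of fragments between libraries were scaled by these floors.

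Peaks were called shared when the intervals overlapped by at least 1 bp; the overlap counts were checked with bedtools 2.31.1, which gave the same numbers. On a simulated list holding 59.4% of the vehicle intervals, 59.4% were found to overlap. Chance overlap was measured over 100 random placements of the GSK2879552 intervals between the first and last peak of each chromosome. For fragment comparisons, shared peaks were reduced to mutual best partners, referred to as pairs. Positions with a local background of 25 fragments or more were termed high-background; this limit, and the comparison of fragments over pairs, were chosen after the data were examined. A limit of 10 was used first and was raised after its values were seen. The interval of the ratio of peak numbers is the exact binomial interval of the 2 counts, taken as independent. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. With 1 peak list per group there is no measure of spread between cultures, so no test between the groups was made and no p-value is given. All differences are between these 2 libraries.

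Before the data were examined, the groups, the overlap rules, the alternatives and the peaks to be named were fixed. The named peaks are the 10 shared peaks with the highest vehicle −log10 p and the 10 peaks of each list alone with the highest −log10 p in their own list; of those in the GSK2879552 list alone, the first 8 are given. Alternatives fixed then comprised stricter thresholds, other overlap rules, joined intervals, other rankings and a restriction to the chromosomes 1 to 22 and X. Planned work on genes near peaks, on 12 fixed gene lists and on sequence motifs was not done, because no hg19 genome or annotation was used here; peaks are therefore identified by position. Coordinates are hg19 and counted from 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.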

Results

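FOXA2 is a forkhead transcription factor that binds and opens compact chromatin, and PC3 is an androgen-independent prostate cancer cell line. GSK2879552 is an inhibitor of the histone demethylase LSD1 (KDM1A). To ask whether FOXA2 occupancy of the genome differs when LSD1 is inhibited, FOXA2 ChIP-seq peaks were compared between PC3 cells given vehicle and cells given 50 µM GSK2879552 for 4 hours. Each group provided 1 peak list from 2 sequencing lanes. If the peak caller's background was made without a control library, the depth of the libraries was close: the background corresponded to 6.17 reads per kb in the vehicle library and 6.44 reads per kb in the GSK2879552 library, a ratio of 1.04.

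Fewer FOXA2 peaks were called after GSK2879552. The vehicle list held 21308 peaks covering 5.82 Mb, and the GSK2879552 list held 14846 peaks covering 3.82 Mb. The number of peaks was thus 30.3% lower, at a ratio of 0.697 (95% interval 0.682 to 0.712, counting error only and treating the lists as independent), and the ratio of covered length was 0.657. Peaks were narrow in both lists, with a median width of 258 bp (interquartile range 209 to 313) in vehicle and 242 bp (196 to 296) in GSK2879552. The lower number was seen on each of the 23 chromosomes with 100 or more vehicle peaks, where the ratio of peak numbers ranged from 0.646 on chromosome 13 to 0.771 on chromosome 16. Chromosome 2 carried the most peaks in both lists, 2098 in vehicle and 1408 in GSK2879552, followed by chromosome 3 with 1949 and 1387.

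The peaks called after GSK2879552 lay largely within the vehicle set. Of the GSK2879552 peaks, 13244 (89.2%, 95% interval 88.7 to 89.7) overlapped a vehicle peak and 1602 did not. Of the vehicle peaks, 13217 (62.0%, 61.4 to 62.7) overlapped a GSK2879552 peak and 8091 did not. Randomly placed intervals overlapped 0.375% of vehicle peaks on average (range 0.300 to 0.460 over 100 placements). By chromosome, the overlapped share of vehicle peaks ran from 55.7% (51.4 to 59.9) on chromosome 13 to 67.1% (61.4 to 72.5) on chromosome 16. With the vehicle list shortened to its strongest 14846 peaks, 77.2% (76.5 to 77.9) overlapped a GSK2879552 peak. Among the strongest 1000 of each list, 73.6% (70.8 to 76.3) overlapped each other.

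The 1000 strongest vehicle peaks all overlapped a GSK2879552 peak (95% interval from 99.6%). Of the 10 shared peaks with the highest vehicle −log10 p, 5 lay on chromosome 10. The strongest shared peak was at chr10:33444863-33445489, where 308 fragments covered the summit in vehicle and 256 in GSK2879552. At chr10:76635608-76636074 the numbers were 242 and 197. The site at chr10:33553128-33553559 had 230 fragments in vehicle and 189 in GSK2879552, and the site at chr8:126442300-126442669 had 180 and 138. Vehicle and GSK2879552 fragments numbered 198 and 168 at chr12:28174653-28175105, 170 and 127 at chr10:80218761-80219147, 180 and 143 at chr10:76559478-76560011, and 180 and 137 at chr14:68846484-68846865. Both remaining sites differed less, with 178 and 172 fragments at chr9:69710816-69711370 and 347 and 332 at chr1:121483987-121485488. The last of these had a local background of 49.3 fragments in vehicle and so belonged to the high-background positions. Its numbers, 347 and 332, were the largest in the vehicle and GSK2879552 lists. Duplicate removal, if it was done, would hold fragment numbers down most at such dense summits. The small difference at chr1:121483987-121485488 therefore does not show that this site was less affected. All 10 sites had fewer fragments after GSK2879552, with log2 ratios from -0.42 to -0.05. They were chosen by their vehicle values, which by itself favours lower numbers in the other list.

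In the window chr10:33400001-33600000, which holds the strongest and the third strongest shared peaks, 17 vehicle and 12 GSK2879552 peaks were called. The 12 overlapped vehicle peaks had at least 31 fragments at the summit, and the 5 peaks found in vehicle alone had at most 45. Local backgrounds in this window reached 16.3 fragments in vehicle and 15.1 in GSK2879552.

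**Figure D1:**
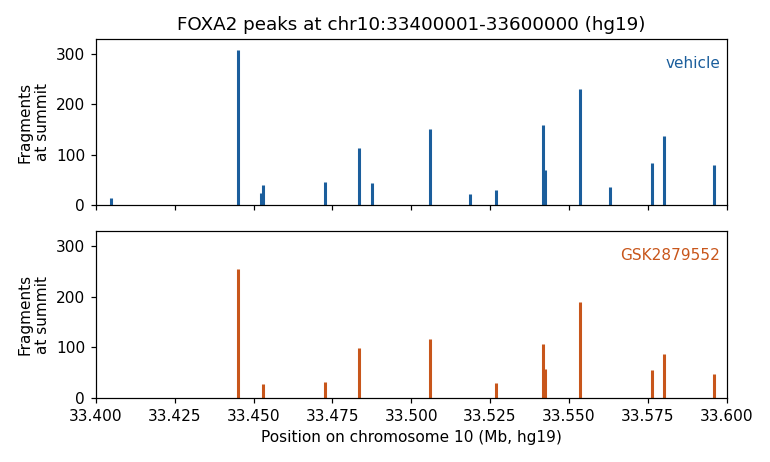
FOXA2 peaks in the window chr10:33400001-33600000 (hg19), with position in Mb on the x axis and the number of fragments at each peak's summit on the y axis, for the vehicle list (top) and the GSK2879552 list (bottom). Each line is 1 peak; the tallest stands at 308 fragments in vehicle and 256 in GSK2879552, and 5 of the 17 vehicle peaks have no overlapping line in the lower panel.

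Vehicle peaks with no GSK2879552 counterpart were weaker sites. They had a median of 14 fragments at the summit (interquartile range 12 to 17), against 24 (17 to 35) for shared vehicle peaks, and a median fold enrichment of 5.77 against 8.41. The strongest vehicle-only peak, at chr5:172994619-172994887, had 33 fragments and a fold enrichment of 13.2, and the nearest GSK2879552 summit was 54656 bp away. Vehicle-only peaks at chr8:106440742-106441032, chr10:12511451-12511736 and chr18:42101074-42101386 followed, with 43, 31 and 30 fragments. The next, at chr10:36918491-36918771 with 54 fragments, had a GSK2879552 summit 773 bp away, and that at chr18:67583687-67583970 with 34 fragments had one 2083 bp away. At chr16:10678744-10679065, with 29 fragments, the nearest GSK2879552 summit was 1331743 bp away. Vehicle-only peaks at chr1:89197295-89197620, chr1:234748257-234748536 and chr13:101016188-101016443 had 28, 26 and 29 fragments. None of these 10 was at a high-background position.

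Peaks found only after GSK2879552 were fewer. They had a median of 12 fragments (11 to 15) and a median fold enrichment of 5.43, against 19 fragments (14 to 27) and 6.84 for shared GSK2879552 peaks. The strongest was at chrY:13704203-13704485, with 24 fragments and a vehicle summit 1155 bp away. This peak lay close to the dense window chrY:13800001-14000000, which held 16 vehicle and 14 GSK2879552 peaks. Whether reads there were placed uniquely was not tested. The second was chr7:42685614-42685871 with 27 fragments, where the nearest vehicle summit was 166166 bp away. The third, at chr19:27740091-27740259, had 86 fragments over a local background of 27.5, a high-background position. GSK2879552-only peaks at chr1:224240067-224240294, chr19:27906136-27906429 and chr19:23548142-23548335 had 25, 21 and 20 fragments. The next were chr5:133728109-133728327 with 19 fragments and chr8:39344252-39344503 with 18.

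The share of sites called in both lists was higher the stronger the site. With vehicle peaks ranked by −log10 p and split into 10 equal bins, the weakest bin had a median of 11 fragments, and 19.6% (17.9 to 21.4) of it overlapped a GSK2879552 peak. The share was 53.9% (51.8 to 56.1) in bin 5, 92.6% (91.4 to 93.7) in bin 8 and 98.4% (97.8 to 98.9) in bin 9. In the strongest bin, 2131 of 2131 overlapped, so the interval allows a retained share no lower than 99.8%. Of GSK2879552 peaks, 68.9% (66.5 to 71.2) of the weakest bin and 100% (99.8 to 100) of the strongest bin overlapped a vehicle peak. In the weakest bins of both lists the medians of 11 and 10 fragments are near the smallest number called, 7 in both lists. A site in 1 list alone is one where no peak was called in the other list, not one shown to be unbound there.

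**Figure D2:**
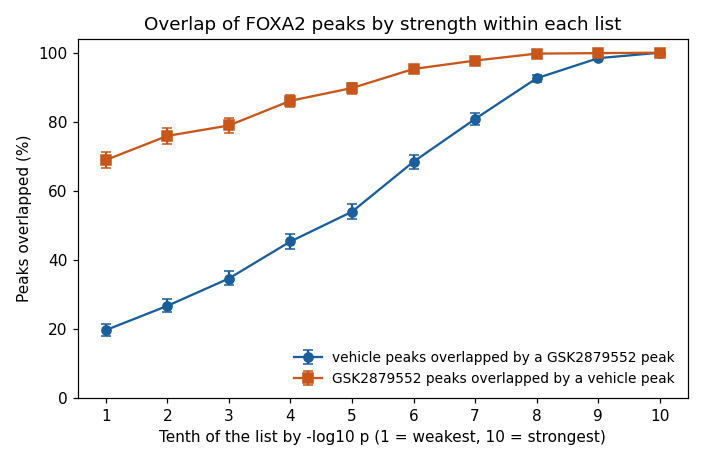
Share of peaks overlapped by a peak of the other list (y axis, percent) in each of 10 equal bins of a list ranked by −log10 p (x axis, weakest to strongest), for vehicle peaks (circles) and GSK2879552 peaks (squares). Bars are exact 95% binomial intervals; vehicle peaks go from 19.6% to 100% and GSK2879552 peaks from 68.9% to 100%.

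Sites occupied in both conditions carried fewer fragments after GSK2879552. Over 13200 pairs of shared peaks, the median number of fragments at the summit was 24 (interquartile range 17 to 35) in vehicle and 19 (14 to 27) in GSK2879552. The median log2 ratio, scaled for depth, was -0.32 (interquartile range -0.57 to -0.08), a median ratio of 0.798. Without this scaling, the number of fragments was lower after GSK2879552 at 10302 pairs (78.0%), equal at 748 (5.67%) and higher at 2150 (16.3%). It was at least 2-fold lower at 533 pairs and at least 2-fold higher at 6, also without scaling. The median log2 ratio was below 0 on each of the 23 chromosomes, from -0.35 on chromosome 20 to -0.21 on chromosome 16. With pairs split into 10 bins by the geometric mean of their fragments, it was -0.13 in the weakest bin. It was -0.39 in bin 8 and -0.30 in the strongest. Only sites called in both lists form pairs, so weak sites missed in 1 list are not counted. Summits of paired peaks lay a median of 23 bp apart (10 to 44).

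The lowest ratio outside high-background positions was at chr18:33391857-33392157, with 48 fragments in vehicle and 14 in GSK2879552. It was followed by chr6:136002471-136002790 with 40 and 12. The highest was at chr11:34946400-34946574, with 9 fragments in vehicle and 24 in GSK2879552, followed by chr7:4752397-4752587 with 9 and 19. These 4 pairs, and the limit that defines high background, were chosen after their values were seen. High-background positions differed from the remaining pairs: over 162 such pairs the median was 134.5 fragments in vehicle and 130.0 in GSK2879552. Their median log2 ratio was -0.05 (-0.12 to 0.03). Duplicate removal, if it was done, would bring numbers at such dense positions closer together. Their ratio therefore does not show that these positions were unaffected. They held 185 vehicle peaks (0.868% of the list) and 172 GSK2879552 peaks (1.16%).

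**Figure D3:**
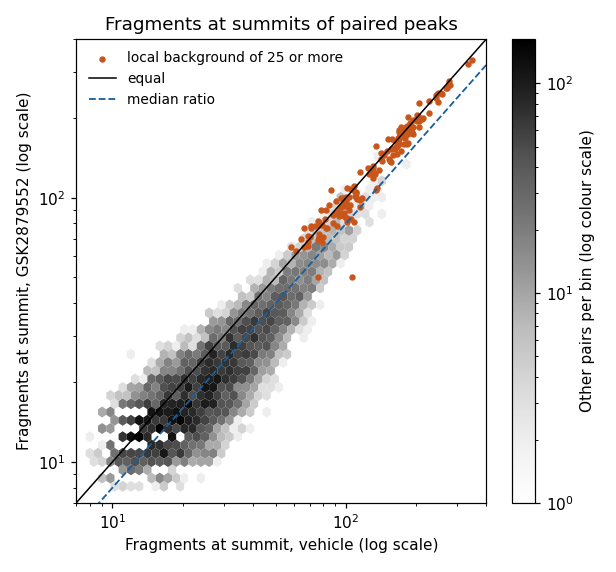
Fragments at the summit in vehicle (x axis) against GSK2879552 (y axis), both on log scales, for 13200 pairs of shared peaks; grey bins count pairs, orange points are the 162 pairs at a local background of 25 fragments or more. The solid line marks equal numbers and the dashed line the median ratio of 0.798, around which the grey bins lie, while the orange points lie near the solid line.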

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

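Fewer GSK2879552 peaks, less covered length and fewer fragments at shared summits were found under each alternative run for them. The lower overlapped share of the longer vehicle list follows from the list lengths, since 13217 vehicle and 13244 GSK2879552 peaks overlap nearly one to one. Holding both lists to a −log10 q of at least 5 gave a ratio of peak numbers of 0.671, a ratio of covered length of 0.638, overlapped shares of 60.3% (vehicle) and 89.98% (GSK2879552), and 17.5% in the weakest of 10 vehicle bins. At a −log10 q of at least 10, with 10909 vehicle and 6529 GSK2879552 peaks left, these were 0.598, 0.578, 55.1%, 92.0% and 14.8%, with 99.8% in the strongest bin and 76.1% at equal list length. A fold of at least 5 gave 0.674, 0.637, 60.1% of vehicle peaks and 76.2% at equal length. With at least 50% of a peak covered, 60.1% of vehicle and 88.5% of GSK2879552 peaks overlapped, with 75.4% at equal length and 17.8% in the weakest bin. With 50% of both peaks these were 59.9%, 86.0%, 75.2% and 17.5%. With summits within 100 bp they were 59.4%, 85.2%, 74.7% and 16.8%, with 99.1% in the strongest bin. With 1 list at a −log10 q of at least 5 and the other as deposited, 67.1% of vehicle and 92.1% of GSK2879552 peaks overlapped; ranking by fold gave 75.1% at equal length. Counting fragments above the local background gave a median log2 ratio of -0.35, and pairs at a −log10 q of at least 10 in both lists -0.31; both settings were chosen after seeing the data, as were a common minimum −log10 p, the removal of high-background positions and pairs by summits within 100 bp, which moved nothing beyond its interval. With the limit of 10 fragments used first for high background, 287 pairs had a median log2 ratio of -0.06, within the interval at the limit of 25. Stricter thresholds by construction leave fewer peaks, and stricter overlap rules fewer overlaps; beyond that, the cause was not tested. Leaving out a lane was not run, since each list covers both lanes. No paired analysis was possible because each group has 1 peak list. Settings for gene location, motifs and gene lists were not run. With 1 list per group, spread between cultures is not measured. Depth may limit the calling of weak sites, which was not tested. It was 6.17 to 6.44 reads per kb if the background was made without a control library.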

Other observations

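All tests below except that of clustering were chosen after the results they bear on, or closely related values, had been seen.

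Of 8691 windows of 200 kb with a vehicle peak, 949 held 5 or more. Summits placed at random between the first and last of each chromosome gave 302.5 such windows on average (259 to 340 over 100 placements); random placement ignores where reads can be mapped. The windows named here were chosen after their values were seen. Outside unplaced or unlocalized sequence, repeat-rich windows near centromeres and the chromosome 10 window already described, dense windows included chr10:63800001-64000000 (15 vehicle and 13 GSK2879552 peaks) and chr5:127200001-127400000 (15 and 12). Others were chr20:50200001-50400000 (12 and 12), chr14:52800001-53000000 (12 and 10) and chr3:187800001-188000000 (12 and 7). Among the 949 windows, 30 had more GSK2879552 than vehicle peaks, and 6 had no vehicle peak overlapped.

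A hypothesis that clustered sites are retained more often was tested. Of 21123 vehicle peaks outside high-background positions, 7261 had another vehicle summit within 12.5 kb. Of these, 64.3% (63.2 to 65.4) overlapped a GSK2879552 peak, against 60.5% (59.7 to 61.3) of 13862 isolated peaks. Within 10 bins of equal strength the mean difference was 1.40 percentage points, below the 5 points set beforehand. Clustered peaks had the higher share in 8 of 10 bins and the lower in 1, and in the strongest bin both shares were 100%; the difference ranged from -2.94 to 7.70 points. The interval of the mean, 0.27 to 2.52 points (counting error only), lies above 0 and under 5, and over bins 1 to 7, where fewer peaks are retained, the mean was 1.79 (0.23 to 3.35). By the rule set beforehand, a mean at or below 5 points counts against the hypothesis, so it was not borne out. The 5 points were too wide a limit for a difference of this size, so a small advantage of clustered sites stays open.

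The shorter GSK2879552 list was weighed against technical explanations. Lower depth would need fewer reads per kb, but the GSK2879552 library had 1.04 times those of vehicle, a value that assumes a background made without a control library. High-background pairs, whose fragment numbers do not rest on this, were lower at 103 of 162. Lower depth gives this direction, and so does a shorter fragment length, which was 168 bp in GSK2879552 and 175 bp in vehicle. Their median log2 ratio was -0.05, against -0.32 at the other pairs. Its bootstrap 95% interval, -0.06 to -0.03, treats pairs as independent and does not cover spread between cultures. These pairs cannot decide on depth, because the handling of duplicate reads is not given. The largest fragment numbers, 347 in vehicle and 332 in GSK2879552, lie just under the most that 1 read per position and strand allows. Duplicate removal would hold fragment numbers down most where fragments are dense. A stricter threshold is argued against by a ratio of peak numbers of 0.653 with both lists held to a −log10 p of at least 10, which removes 5791 vehicle and 4708 GSK2879552 peaks. Loss limited to sites near the threshold is argued against by the strongest of 10 bins of the GSK2879552 list, where the median log2 ratio of fragments was -0.28 (interquartile range -0.45 to -0.10), with 1246 of 1485 pairs lower.

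For the lower fragment numbers at shared summits, a difference in scaling or fragment length touching all positions alike would lower high-background pairs equally. Their median log2 ratio was -0.048. This cannot decide, because the handling of duplicate reads is not given. Duplicate removal, if it was done, would bring numbers at such dense positions closer together in both libraries. A loss at a minority of the shared sites, with the others split evenly, would leave at most 75% of pairs lower, and 78.0% (77.3 to 78.7) were. That even split was assumed and not measured. High-background pairs, with a ratio near even, were themselves lower at 103 of 162. The excess over 75% therefore cannot decide whether the loss was at a minority of sites. Whether 1 common factor covers all sites stays open: over 3354 pairs with 60 or more fragments in all the dispersion about a common ratio of 0.775 was 0.872, lower than counting error gives, so this measure has no known value for no extra spread. A lower yield of 1 immunoprecipitation and lower FOXA2 occupancy under LSD1 inhibition both stay open, since each group is 1 list.

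On chromosome 10, 5 bins of 1 Mb, chosen for their vehicle background and leaving out the bin next to the centromere, had a high local background in both libraries. Median backgrounds in vehicle and GSK2879552 were 6.21 and 7.27 fragments at chr10:33000001-34000000, 5.49 and 6.13 at chr10:76000001-77000000, 5.64 and 5.75 at chr10:78000001-79000000, 5.49 and 6.28 at chr10:75000001-76000000, and 5.29 and 5.28 at chr10:63000001-64000000. The median over 1158 bins with 8 or more vehicle peaks was 1.67. Reads of the peaks themselves or of listed neighbours are argued against as the whole cause by the GSK2879552 library, whose values did not rank the bins but had been seen: 13 peaks of 25 or fewer fragments with no other summit within 10 kb had a median background of 4.28 (3.93 to 4.92), which is 3.0 times that of 7833 such peaks elsewhere (1.43, 1.18 to 1.76). A candidate explanation is extra copies of these stretches in PC3 DNA, which was not tested, since no input DNA was analysed here; the median log2 ratio of fragments there was -0.36 over 109 pairs, so the lower numbers after GSK2879552 were seen in these stretches too.

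Peaks were also listed on the mitochondrial chromosome, 6 in vehicle and 3 in GSK2879552. Of the vehicle high-background peaks, 36 were on the unlocalized chromosome 9 sequence chr9_gl000199_random and 22 lay between positions 46386711 and 46435578 of chromosome 16.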
